A study of Mus musculus with 18 samples.

How the data were processed

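MicroRNAs were measured in mammary tumours of F1 mice from crosses between the MMTV-PyVT transgenic FVB/N line, in which the mammary epithelium expresses the polyoma virus middle T antigen, and 18 AKXD recombinant inbred strains. AKXD strains are inbred lines that each carry a different mosaic of the AKR and DBA/2 genomes. For each strain 1 pool of tumour total RNA was hybridised to 1 two-colour custom Agilent microRNA array. Per the labels' protocols, RNA was isolated with the mirVana kit and labelled with the miRCURY LNA kit. The tumour RNA carried Hy3 (green) and the reference RNA, from assorted tissues of Swiss Webster mice, carried Hy5 (red) on every array. Dyes were not swapped, so a dye effect is part of every ratio.

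The scanner files hold spot and local background intensity on a linear scale, deposited as read by Agilent Feature Extraction, per the submitters' processing notes. Per the file headers of 17 arrays its version was 9.5.1.1. The file of strain 2 has no settings block, so its version and slide are not given in the sources used here. The number of mice behind a pool is likewise not given. The same files hold, per the file headers, processed intensities after background subtraction and dye normalization, a log10 ratio of red over green, and flag columns with another kind of value, 0 or 1, for spots well above background, saturated or outlying. The authors' deposited series table holds log2 values that matched the mean over the 4 spots of a probe of the scanner's log ratio of reference over tumour on all 18 arrays, with differences of at most 0.000028 and r = 1.000000. Scale and direction of that table are therefore known. Its column medians ran from 0.00 to 0.346 and it was turned to tumour over reference before use.

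Each array carried 1932 spots. Of 349 probes outside the controls, 334 named exactly 1 mouse miRNA and 15 named none. The latter were left out of tests. No spot was saturated. Names are those of the array design, and some are older than current usage (miR-122a, miR-124a, miR-128a). A list entry had to match the array's name after the arm suffix was removed, so a probe named miR-146 was not counted as miR-146a. The background was corrected with normexp (offset 50) on the mean spot and median background intensities, ratios were normalised within each array by loess, and the 4 spots of a probe were averaged, without spots marked as outliers. Control and marked spots had weight 0 in loess. A miRNA counted as above background on an array when at least 2 of its 4 spots were well above background, a limit set after the files had been seen. All values are log2(tumour / reference), so that values above 0 are higher in tumour. The main test kept miRNAs above background in either channel on at least 9 of 18 arrays (314 miRNAs). Measures of the spread between strains kept those above background in the tumour channel on at least 9 arrays (284 miRNAs).

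The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. A miRNA was counted as higher or lower at an adjusted p under 0.05 and a mean of at least 1 either way. The reference was a single RNA, so this test describes the tumours against that RNA and leaves out its own spread. For a miRNA above background on no array of the tumour channel the fold is given as a lower bound, against the lowest signal of the miRNAs above background on each array, per channel after loess and Aquantile, and is open to dye bias. Fixed miRNA lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over the 18 lists with at least 3 measured members. No measured member of the miR-302 cluster list passed the filter. A probe named miR-302 did pass, but its name matched no entry of that list and it was not counted.

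With 1 pool per strain, differences between strains have no replicate and are given as values with no test. The SD over the pools, the SD between the 4 spots of an array and the share of variance between arrays describe them. Whether members of a list varied together over pools was tested by their mean pairwise Pearson r, against 10000 random lists matched on intensity, one-sided. List scores, the mean of z-scored members, were related by Pearson r and Spearman rho with permutation tests of 100000 resamples, two-sided, over 55 pairs. The calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The p-values of limma, fry and the permutation tests measure the spread between single pools. That spread holds the strain, the mice pooled, the labelling and the array together. Camera instead sets a list against the other miRNAs. List covariation is set against random lists, and neighbouring genes against shuffled gene labels. Those p-values do not measure the spread between pools.

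The files gave 8 arrays on slide A (strains 7 to 18), 8 on slide B (strains 20 to 28) and strain 3 alone on slide C. By the scan dates strain 3 was also scanned in another session than slides A and B, and no session is given for strain 2. Slides A and B were compared with limma. Neither strain 3 nor strain 2 shares a known slide with another array, and no within-slide value can be had for them. The lowest correlation between 2 arrays was 0.805 and the highest 0.986. The closest pair, strains 14 and 24, differed by an SD of 0.180 where the spots alone would give 0.0759, so no arrays were merged.

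Named miRNAs followed a rule written before the data were examined. They are the 12 highest and 12 lowest means among counted miRNAs of 1 sign on at least 16 arrays, the 12 largest SDs between strains, every measured member of the miR-290 cluster, and up to 4 members of each other list by absolute mean. Any other miRNA named was chosen after its values were seen. The methods were tested on simulated data. With 314 miRNAs, 100% of means of 1.5 and of 2 were recovered and 0% of unchanged miRNAs were counted. The planted means lay past the minimum of 1 and the unchanged ones at 0, so these rates do not cover means near 1. Slide shifts of 1 were recovered in 98%, with 0.8% of unchanged miRNAs counted as differing between slides. With 284 miRNAs, 100% of planted covarying lists and 95% of planted score relations were recovered, against 0.3% of other lists and 0.28% of other relations. Apart from what was planted, the simulated miRNAs varied independently and no array was set apart from the rest. These rates of false calls therefore need not hold for the real arrays. Alternatives changed the background offset, the normalization, the filter, the channel, the slide block and the arrays left out. The arrays' number limits the precision.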

Results

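Tumour RNA pools of 18 AKXD F1 crosses were profiled for miRNA levels against 1 common reference RNA. The strains share the tumour-inducing transgene and differ in the inherited background, so the design asks which miRNAs differ in mammary tumours between genetic backgrounds. All 18 pools form 1 group with 1 pool per strain, named here by strain number. On the arrays of 16 strains 270 to 311 of 334 miRNAs were above background in the tumour channel and at least 299 in the reference channel. The arrays of strains 2 and 3 had 176 and 163 in the tumour channel and 195 and 240 in the reference channel. Ratios on these 2 arrays were compressed, with slopes of 0.471 and 0.469 on the mean of the others, against 0.931 to 1.08 for the other 16.

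The first comparison sets the tumours against the reference. Epithelial miRNAs led those higher in tumour. The miR-200 family, which maintains the epithelial state by repressing ZEB1 and ZEB2, was higher throughout, with means of 3.78 ± 0.41 (SD, n = 18) for miR-141, 3.09 ± 0.44 for miR-200c, 2.59 ± 0.21 for miR-200b, 2.52 ± 0.17 for miR-200a and 2.21 ± 0.23 for miR-429. The highest mean was that of miR-146b, a regulator of inflammatory signalling, at 3.79 ± 0.34, a 13.9-fold excess (limma adjusted p = 3.64e-20). In the 12 highest were also miR-31 (2.48 ± 0.64), miR-205 (2.27 ± 0.52), miR-148a (2.26 ± 0.33) and miR-720 (1.96 ± 0.33), along with miR-182 and miR-96 of the miR-183 cluster, at 2.39 ± 0.54 and 2.27 ± 0.54. All 12 were higher on 18 of 18 arrays.

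The lowest means belonged mostly to miRNAs known from other tissues. The neuronal miR-124a was at -7.40 ± 1.34, 169-fold lower (limma adjusted p = 3.65e-15), miR-128a at -4.81 ± 1.00, miR-128b at -4.79 ± 1.03, miR-9 at -3.38 ± 1.30 and miR-138 at -2.99 ± 0.86. The liver miRNA miR-122a was at -5.12 ± 1.04 and miR-194, of liver and gut, at -3.27 ± 0.64. The p53-responsive miR-34b and miR-34c were at -4.65 ± 0.92 and -4.56 ± 0.75. The erythroid miR-451 was at -3.95 ± 0.49, the heart miRNA miR-499 at -3.43 ± 0.94 and miR-335 at -2.75 ± 0.79. All 12 were lower on 18 of 18 arrays. In the tumour channel miR-499 was above background on only 3 of 18 arrays, and its mean moved with the background correction, to -4.27 with an offset of 10 and -6.83 with the scanner's log ratio.

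With limma 29 of 314 miRNAs were higher and 59 lower. Without strains 2 and 3, an alternative chosen after seeing the data, the counts were 35 and 65. With the scanner's own log ratio they were 23 and 113, or 16.9% of calls higher against 33.0%, and the median of all miRNAs went from 0.04 to -0.39, so that means are relative to the normalization. Sizes of several strongly lower miRNAs moved by more than that, with miR-124a at -9.36, miR-34b at -5.91, miR-495 at -4.30, miR-300 at -3.23, miR-127 at -3.12, miR-381 at -3.21 and miR-192 at -4.51 with the scanner's log ratio. Their folds thus depend on the background correction and normalization. Others moved less, such as miR-451, at -4.09 against -3.95.

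**Figure D1:**
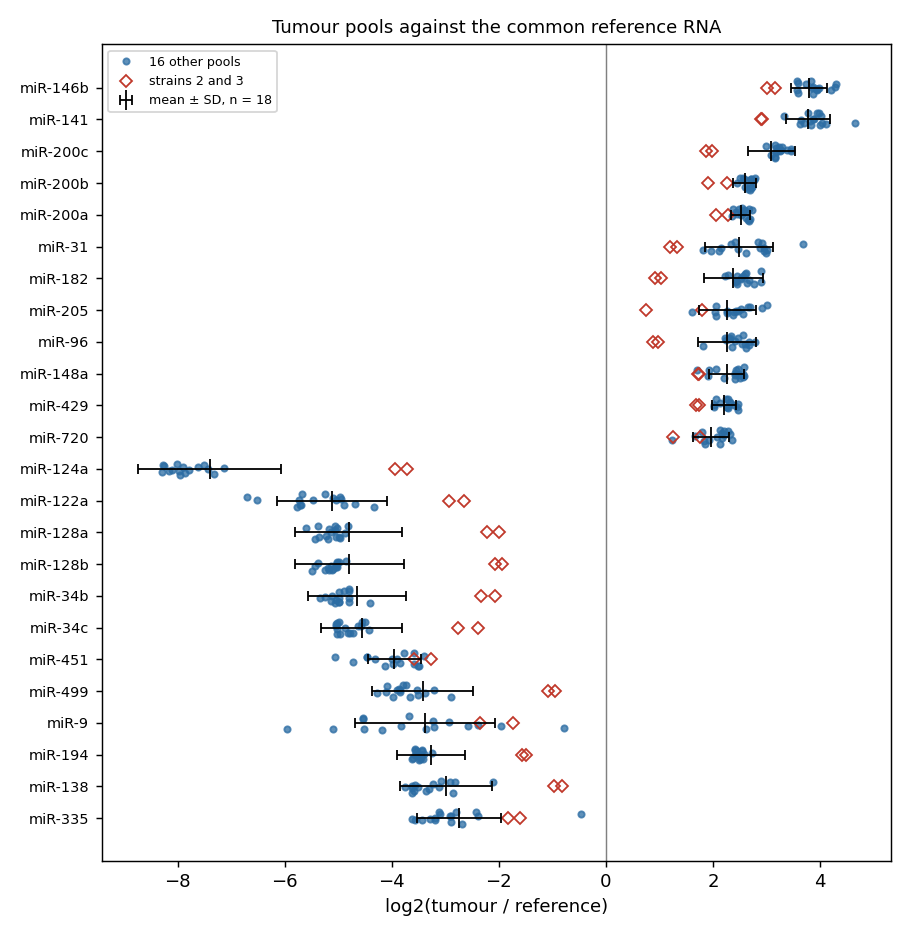
Log2(tumour / reference) on the x axis for the 12 highest and 12 lowest miRNAs. Blue points are 16 pools, red diamonds strains 2 and 3, and black bars the mean ± SD over 18 pools; the diamonds lie nearer 0 than the mean for every miRNA drawn, as for miR-124a, with -3.93 and -3.72 against a mean of -7.40.

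By list, 6 of 7 epithelial miRNAs were higher and the remaining one, miR-203, was at -0.02 ± 0.67. The count was also 6 when adjusted over the list alone. Of 11 brain miRNAs 7 were lower, and 7 when adjusted over the list alone. One of them, miR-137, was not well above background in the tumour on any array and was at least 4.31-fold lower (limma adjusted p = 1.66e-11). Both miR-203 and miR-137 were picked after their values were seen. Of 43 miRNAs of the imprinted Dlk1-Dio3 cluster 9 were lower, and 9 when adjusted over the list alone, led by miR-495 (-2.32 ± 0.71), miR-300 (-2.16 ± 0.66), miR-127 (-2.12 ± 0.55) and miR-381 (-2.05 ± 0.65). These 3 lists passed camera with a preset correlation, at adjusted p of 0.0059, 0.0059 and 0.0335. They had an adjusted p = 0.343 with an estimated correlation, as did most lists, and 0 of 18 lists passed then. With fry, which asks only whether members lie on balance to 1 side of the reference, the largest adjusted p of the 18 was 0.0121.

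The other 15 lists did not pass camera, and for each of them the counts over all miRNAs and adjusted over the list alone were equal. Of 6 muscle miRNAs 5 were lower (camera adjusted p = 0.0627), with miR-1 at -1.89 ± 1.07, miR-133b at -1.77 ± 0.99 and miR-208, not well above background in the tumour on any array, at least 5.77-fold lower (limma adjusted p = 3.25e-11). All 3 erythroid miRNAs were lower (camera adjusted p = 0.0644), with miR-144 2.83-fold lower and miR-486 at -1.30 ± 0.46. Of 4 endothelial miRNAs 3 were lower (camera adjusted p = 0.0519), miR-10b (-1.73 ± 0.49), miR-126-5p (-1.37 ± 0.37) and miR-221 (-1.20 ± 0.28). Of 7 stromal miRNAs the smooth muscle pair miR-143 (-1.75 ± 0.41) and miR-145 (-1.69 ± 0.31) were lower and 5 did not pass (camera adjusted p = 0.746). Of 5 leukocyte miRNAs miR-150 (-1.86 ± 1.16) and miR-142-5p (-1.0 ± 0.76) were lower (camera adjusted p = 0.0662). The call of miR-142-5p lay at the minimum size and was lost on leaving out any of 10 pools, with a mean of -0.93 without strain 10. Of 6 liver and pancreas miRNAs 3 were lower (camera adjusted p = 0.245), miR-122a, miR-194 and miR-192 (-2.43 ± 0.83). Of 3 miR-29 family members 2 were lower, miR-29b (-1.56 ± 0.48) and miR-29c (-1.15 ± 0.26), with a camera adjusted p of 0.0667. Of 3 miR-34 family members 2 were lower and miR-34a was at -0.24 ± 0.33 (camera adjusted p = 0.0718).

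Of 12 miRNAs of the miR-17-92 cluster and its paralogues, which drive proliferation, miR-19a alone was higher (1.11 ± 0.47, camera adjusted p = 0.0718), and its mean was 0.97 with the scanner's log ratio, under the minimum. Of 3 miR-183 cluster members 2 were higher and miR-183 was at 0.98 ± 0.39 (camera adjusted p = 0.0662). Without strains 2 and 3 miR-183 was at 1.09 and passed. Its mean was 1.49 with an offset of 10 and 1.83 with the scanner's log ratio, but 0.83 with median centring. Of 9 let-7 family members 0 passed (camera adjusted p = 0.881), with let-7b at 0.85 ± 0.15 and let-7g at -0.64 ± 0.20. The let-7 median was -0.07 while its mean was 0.05 and camera's direction upward. Of 5 Sfmbt2 cluster members 0 passed (camera adjusted p = 0.0627). Among these miR-297 was at 0.93 ± 0.35, miR-669a at 0.92 ± 0.33 and miR-669b at 0.89 ± 0.34. Past the minimum were miR-297 and miR-669a without strains 2 and 3, and miR-297, miR-669a and miR-669b with an offset of 10. Of 6 miRNAs of an X-linked cluster 2 were lower, miR-503 (-1.52 ± 0.50) and miR-424 (-1.47 ± 0.34), with a camera adjusted p of 0.0928. Of 16 miRNAs drawn from the breast cancer literature 3 were higher, including miR-31 and miR-205, and 7 lower, including miR-9 and miR-335 (camera adjusted p = 0.0627).

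The miR-290 cluster, expressed in early embryos and embryonic stem cells, was of interest to the study as a locus with inherited variation. Of its 7 measured members miR-290 was higher, at 1.06 ± 0.42 (limma adjusted p = 1.10e-09, higher in 18 of 18 pools). The means of the others were 0.58 ± 0.25 for miR-294, 0.42 ± 0.14 for miR-292-5p, 0.27 ± 0.17 for miR-291b-5p, 0.24 ± 0.17 for miR-293 and 0.19 ± 0.10 for miR-291a-5p. In the tumour channel miR-291a-5p and miR-291b-5p were above background on 11 arrays, and miR-295 was not well above background on any array, so that no fold is given for it. The list did not pass camera (adjusted p = 0.0994), and 1 member was higher when adjusted over the list alone. The mean of miR-290 was under the minimum of 1 with median centring (0.74) and with the scanner's log ratio (0.79), and that of miR-293 was -0.26 with the latter.

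**Figure D2:**
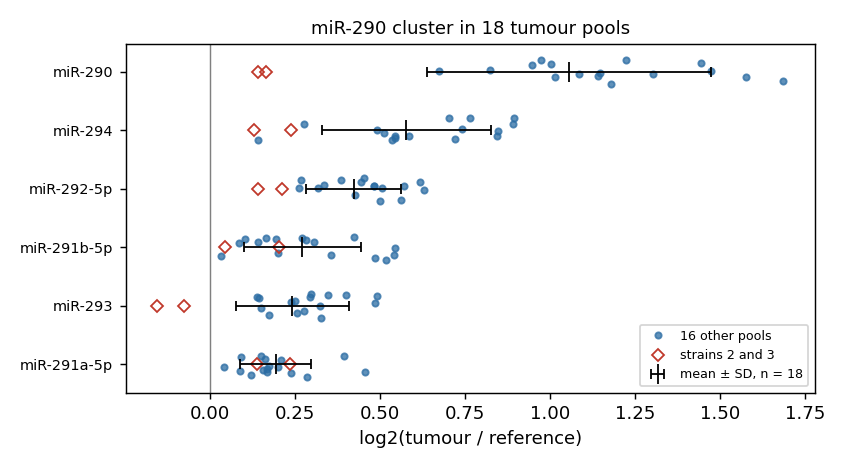
Log2(tumour / reference) on the x axis for the 6 miR-290 cluster members above background in the tumour channel. Blue points are 16 pools, red diamonds strains 2 and 3, and black bars the mean ± SD over 18 pools; miR-290 spans 0.68 to 1.69 in the 16 pools and lies at 0.14 and 0.17 in strains 2 and 3.

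The second question is how far strain pools differed. Over 18 pools the median SD of a miRNA was 0.26, against a median SD between spots of 0.10, which leaves out differences between arrays. Over 16 pools the reference channel, with the same RNA on every array, had a median SD of 0.24, the tumour channel 0.33 and the ratio 0.22. Over 18 pools 38 of 284 miRNAs had an SD of at least 0.5. The 12 largest SDs were those of miR-124a (1.34), miR-9 (1.30), miR-150 (1.16), miR-1 (1.07), miR-204 (1.06), miR-122a (1.04), miR-128b (1.03), miR-128a (1.00), miR-133b (0.99), miR-34b (0.92), miR-138 (0.86) and miR-192 (0.83). Without strains 2 and 3, 17 miRNAs had an SD of at least 0.5, and 6 of the 12 stayed among the 12 largest. The SD of miR-124a was then 0.35 and that of miR-128b 0.17.

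The muscle miRNAs miR-1 and miR-133b varied widely. In the 16 pools miR-1 ranged 11.2-fold, from -4.10 in strain 7 to -0.62 in strain 11, with -3.13 in strain 9, -3.61 in strain 10 and -2.61 in strain 28. The range of miR-133b was 10.1-fold, lowest in strain 7 and highest, at -0.67, in strain 20. The skeletal muscle miRNA miR-206, picked after its values were seen, ranged only 2.30-fold, with an SD of 0.31 over the 16 pools (rank 54 of 284). The lymphocyte miRNA miR-150 ranged 10.6-fold, from -3.46 in strain 23 to -0.06 in strain 11, and stood at -0.14 in strain 25, -0.51 in strain 27, -0.84 in strain 14 and -0.97 in strain 24. In the same 5 pools miR-142-5p, of blood cells, lay between -0.52 and 0.36, against a median of -1.31 over 18 pools, but it was also at -0.31 in strain 23, where miR-150 was lowest and the reference channel of miR-142-5p deviated by -1.80 from its median in the other pools of slides A and B. Neural miR-9 ranged from -5.95 in strain 18 to -0.79 in strain 9, and miR-204 from -2.69 in strain 24 to 1.11 in strain 21. By contrast miR-290 had an SD of 0.27 over the 16 pools, rank 80 of 284, and a 2.02-fold range from strain 23 to strain 10. The other detected members had SDs of 0.11 to 0.22. Their mean ratios moved with the background offset, as that of miR-292-5p, from 0.42 to 0.65 with an offset of 10. That of miR-290 moved likewise, from 1.06 to 1.35. These SDs may therefore depend on the background correction too. No strain value has a replicate, and strain and array cannot be told apart.

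**Figure D3:**
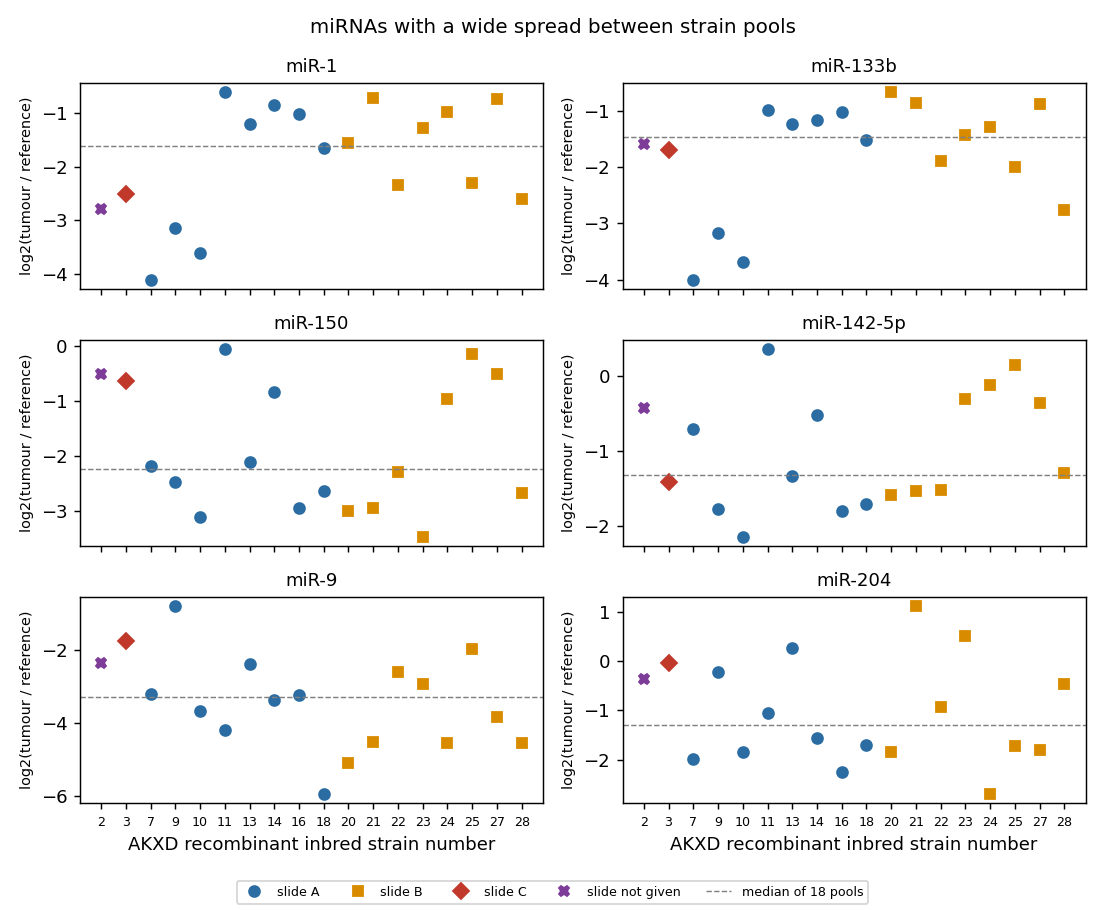
Log2(tumour / reference) on the y axis against AKXD strain number for 6 miRNAs with a wide spread. Each point is 1 pool, with colour and shape for the slide and a dashed line for the median of 18 pools; miR-1 and miR-133b are lowest in strains 7, 9 and 10.

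Counted per strain, 136 values lay at least 1 from the median of the 18 pools, 31 of them in strain 2, 35 in strain 3 and 23 in strain 23. The other 15 pools had 1 to 7 each. In strain 23, 20 miRNAs were above and 3 below, and its array correlated less with the other pools (r = 0.928 across miRNAs, which are not independent replicates) than the other 15 arrays of slides A and B (0.969 to 0.988). The reference channel moved with this. On the array of strain 23 its median intensity was 292.5, against at least 378.5 on the other 15, and for 17 of the 20 miRNAs it deviated more than the tumour channel. The median deviation of the 20 from the other 15 pools was 0.16 in the tumour channel and -1.16 in the reference channel, in a look made after the counts were seen. The tumour channel was higher by at least 1 for 3 of the 20, miR-204 (2.61), miR-335 (1.59) and miR-203 (1.26).

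Of 18 lists, 11 had members that varied together over the 18 pools more than random lists, and 10 did without strains 2 and 3. The mean pairwise r over the 16 pools was 0.867 for 4 muscle miRNAs, 0.716 for 5 Sfmbt2 cluster miRNAs, 0.606 for the miR-183 cluster, 0.443 for 12 miR-17-92 miRNAs and 0.435 for 9 let-7 miRNAs. The adjusted p was 0.00216 for the miR-183 cluster and 0.00045 for the other 4, whose p of 0.0001 is the smallest that 10000 random lists can give. For stromal, leukocyte and endothelial miRNAs it was 0.318, 0.311 and 0.338 (adjusted p = 0.00480, 0.0300 and 0.0495), for the miR-34 family 0.604 (adjusted p = 0.0072, but 0.478 and adjusted p = 0.0529 over 18 pools) and for the X-linked cluster 0.276 (adjusted p = 0.0178). The let-7 list did not pass over 17 pools without strain 23 (0.207, adjusted p = 0.0793). The X-linked list, with an adjusted p of 0.0468 over 18 pools, did not pass on leaving out any 1 of 8 pools, strains 7, 10, 11, 14, 16, 21, 22 and 27 (adjusted p from 0.0501 to 0.0751). The epithelial and brain lists passed with 18 pools, at 0.435 and 0.406, and not with 16, at 0.0650 and 0.0591. The miR-290 cluster did not pass, with a mean r of 0.342 over 18 pools (adjusted p = 0.0584) and 0.0947 over 16 (adjusted p = 0.233). Pairs of probes that share at least 60% of their bases were sought only among genes within 10000 bp of each other. The Sfmbt2, miR-183, miR-17-92, let-7, miR-34, X-linked and epithelial lists hold such pairs. Probes of genes farther apart were not compared. The random lists were matched on intensity only, so similar probes were not excluded as a source of the r of any list.

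Most relations between list scores that passed over 18 pools were smaller or turned without strains 2 and 3, which lie apart from the rest, as that of epithelial and brain scores, with r = -0.864 over 18 pools and 0.430 over 16. With 18 pools 15 of 55 relations passed for r and 3 for rho, and over the 16 other pools 0 did for r and 1 for rho, with 7 and 5 at an unadjusted permutation p under 0.05. Among the 15, stromal and miR-17-92 scores (r = -0.593, adjusted p = 0.0377, and rho = -0.705, adjusted p = 0.0453, over 18 pools) and endothelial and leukocyte scores (r = 0.716, adjusted p = 0.0134, and rho = 0.699, adjusted p = 0.0453) did not rest on these 2 strains, having an r of similar size without them. The 3 relations with the smallest permutation p for r over the 16 pools follow. Leukocyte and imprinted cluster scores had r = -0.723 (p = 0.00144, adjusted p = 0.0792) and rho = -0.650 (p = 0.00726, adjusted p = 0.113), with -0.679 within slide A, -0.774 within slide B and -0.553 without strains 11 and 25. Over 18 pools the same scores had r = 0.024 (permutation p = 0.923) and rho = -0.317 (permutation p = 0.201), so this relation was seen only without strains 2 and 3. Stromal and miR-17-92 scores had r = -0.655 (p = 0.00627, adjusted p = 0.152) and rho = -0.768 (p = 0.00064, adjusted p = 0.0352), with -0.889 in slide A, -0.230 in slide B and -0.449 without strains 10 and 11. Endothelial and leukocyte scores had r = 0.633 (p = 0.00827, adjusted p = 0.152) and rho = 0.647 (p = 0.00820, adjusted p = 0.113), with 0.710 in slide A, 0.596 in slide B and 0.631 without strains 7 and 23.

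Between slides A and B 3 of 284 miRNAs differed with limma, and 55 had an unadjusted p under 0.05. These were miR-487b (0.54 in slide A, 0.08 in slide B, adjusted p = 0.00344), miR-715 (1.20 and 0.78, adjusted p = 0.00934) and miR-23b (0.58 and 0.81, adjusted p = 0.0404). These 3 were picked after their values were seen. With limma 0 miRNAs differed after median centring (24 at an unadjusted p under 0.05) and 0 in the tumour channel alone (36).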

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

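Alternatives without strains 2 and 3 or 23, and the slide comparison in the reference channel, were tests chosen only after the results were seen. The others were planned. Scaling between arrays, as run here, divided the log ratios of each array by a factor set by their median, not by their spread. It did not bring the arrays to a common spread, so its counts below are no check on the other results. Counts of miRNAs higher and lower than the reference were 154 and 137 with no minimum size, 44 higher after scaling between arrays, and 113 lower with the scanner's log ratio or the authors' deposited series table; leaving out 1 pool gave 26 to 32 higher and 56 to 64 lower. Of 18 lists, 3 passed camera; 0 did with an estimated correlation, 1 of 16 tested with miRNAs above background on all arrays, 5 with median centring, the scanner's log ratio or the series table, 7 after scaling, and 3 to 4 without 1 pool. The epithelial adjusted p ran from 4.15e-05 to 0.0482, brain from 0.0027 to 0.0796 and imprinted from 0.00571 to 0.0885 over the preset alternatives. miRNAs with an SD of at least 0.5 numbered 38, against 86 with the scanner's log ratio, 87 with the series table, 158 after scaling, 198 in the tumour channel alone, 17 with miRNAs above background on all arrays (149 tested), 17 without strains 2 and 3, 11 without strain 23 as well, 15 with slide as a block, which also leaves out strains 2 and 3, and 28 to 41 without 1 pool. Deviations of at least 1 numbered 136, against 289 with the scanner's log ratio or the series table, 745 after scaling, 542 in the tumour channel alone, 62 with miRNAs above background on all arrays, 67 without strains 2 and 3, and 64 for deviations of 1.5. Covarying lists numbered 11, against 7 in the tumour channel alone, 6 of 10 tested with miRNAs above background on all arrays, and 10 to 14 without 1 pool. They numbered 10 without strains 2 and 3, and 9 in the same pools with slide as a block. The let-7 list was lost without strain 23 (adjusted p = 0.0793), the X-linked list without any of strains 7, 10, 11, 14, 16, 21, 22 and 27 (adjusted p = 0.0501 to 0.0751), and the brain list's mean r turned to -0.178 with miRNAs above background on all arrays. Score relations past the threshold numbered 15, against 39 after scaling, 27 in the tumour channel alone, and 0 with the scanner's log ratio, the series table, miRNAs above background on all arrays, or without strains 2 and 3, with or without slide as a block; leaving out 1 pool gave 0 to 17, with 0 without strain 2 and 3 without strain 3. The slide comparison gave 3 miRNAs, against 0 with median centring (24 at an unadjusted p under 0.05 with limma), 0 in the tumour channel alone (36) and 0 in the reference channel (31). With the filter on all arrays fewer miRNAs were tested, and scaling changed the arrays as given above. For the other settings the cause was not tested. The 2 arrays with fewest miRNAs above background limit what can be read of strains 2 and 3. No paired analysis was possible because there is 1 group of pools.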

Other observations

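The tests of strains 2 and 3, of muscle and leukocyte amounts, of miR-290 and its probe, of the muscle reference channel, of the leukocyte reference channel without strain 23 and of slide splits were chosen only after the results were seen, unlike those of neighbouring genes and of the reference channel for leukocyte miRNAs over 16 pools. Pairs of miRNAs whose genes were placed within 10000 bp of each other in GRCm38.p6 varied together over the 16 pools other than strains 2 and 3. Genes were matched by name or synonym, which can place a miRNA at a wrong locus. For instance, miR-298 was paired with miR-296 and also with members of the imprinted cluster such as miR-494. Some pairs may therefore not be true neighbours. Of 284 detected miRNAs 272 matched a gene, and the mean r of 259 neighbouring pairs was 0.227, above the 95th percentile of 0.045 of 10000 shuffles (one-sided p = 0.0001, the smallest they can give). It was 0.238 with slide means removed and 0.275 without strain 23. Among pairs whose probes share under 60% of their bases, 215 in all, the mean r was still 0.171 against a 95th percentile of 0.049, which argues against similar probes as the whole source. A shared primary transcript is a candidate explanation. Examples, chosen for their values, are miR-503 and miR-450, miR-532 and miR-362, miR-497 and miR-195, and miR-221 and miR-222.

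The arrays of strains 2 and 3 gave compressed ratios. Their reference channel, which held the same RNA as elsewhere, correlated at 0.925 and 0.948 with the mean of the others, and the lowest of the other 16 arrays was 0.974. At most 240 miRNAs were above background in it, against at least 299 elsewhere, which argues against strain differences between the tumours alone. The array of strain 3 was also scanned in another session than the other 16, and the session of strain 2 is not given. A batch effect cannot be told apart from the strain here. Array or labelling quality may account for the compression, while strain differences beneath it remain untested. The array of strain 23 was at 0.979 in the same measure and that of strain 27 at 0.974.

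In the tumour channel over 16 pools miR-1 and miR-133b moved together (r = 0.949, adjusted p = 5.3e-05, rho = 0.841, adjusted p = 0.000693; 0.904 without strains 7 and 10, 0.988 in slide A and 0.880 in slide B, 16 pairs tested, permutation tests). The reference channel varied at most 0.154 times as much as the tumour channel for both, which argues against the reference as the source. Differing amounts of muscle tissue in the pools may account for this, but stay open, since the lowest pairwise r, of the skeletal muscle miR-206 with miR-133b, was 0.577 (upper 95% bound 0.834, a bound added once the values were known), with a rho of 0.406 (adjusted p = 0.320) and r = 0.475 without strains 7 and 13. For miR-206 with miR-1 rho was 0.150 (adjusted p = 0.703) and r went from 0.583 to 0.355 without the same strains. By r, miR-206 did pass with miR-1 and miR-133b (adjusted p = 0.0457 for both) and with miR-133a* (0.633, adjusted p = 0.0295). In the ratios over the same pools miR-206 and miR-133b had r = 0.806, and the mean r of the 4 was 0.867. The rho values go against a source shared by all 4 and these r values go with it, so it stays open. The mean tumour channel levels of miR-1 and miR-133b were 12.58 and 11.47 (log2), and miR-206 also stands in the breast cancer list. The levels of miR-150 and miR-142-5p also moved together (r = 0.926, adjusted p = 8e-05, rho = 0.829, adjusted p = 0.000693; 0.870 without strains 11 and 25, 0.929 in slide A and 0.923 in slide B), and leukocytes are a candidate source, but it was the only 1 of 10 leukocyte pairs that passed, and miR-342 with miR-150 had r = -0.119. That lies under the limit of 0 set against this explanation, and it stays open only because the upper 95% bound, again added once the values were known, was 0.400. That bound in turn lies under the r that every pair had to pass in favour of the explanation. The mean levels of miR-142-5p and miR-223 were 11.44 and 10.84 (log2), and miR-155 also stands in the breast cancer list. The reference channel varied up to 0.658 times as much as the tumour channel, for miR-142-5p (0.164 for miR-150), but the array of strain 23 made that value. Without it the highest ratio was 0.204 and the r of this pair 0.921, which argues against the reference as the source in the other 15 pools and leaves it open for miR-142-5p in strain 23. The strain background of the tumour-bearing mice, the design's own difference, stays untested for both.

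The ratio of miR-290 stood above that of its cluster. Over 16 pools its mean r with the other 5 detected members was -0.150, at percentile 31.6 of random lists matched on intensity. Single values ran from -0.59 for miR-293 to 0.481 for miR-292-5p. These members varied less between pools than miR-290, as given above, which limits what a low mean r can decide about the source. Of 283 relations of miR-290 the closest was with miR-296, which lies outside the cluster (r = 0.967, adjusted p = 0.000708, rho = 0.932, adjusted p = 0.00226, permutation tests). It was 0.945 without strains 10 and 13, 0.989 in slide A and 0.882 in slide B, and miR-700, miR-715 and miR-680 followed. The miR-290 probe holds a run of at least 4 guanines or cytosines, and the 33 other miRNAs with such a run had a median r of 0.450 with miR-290, above the 95th percentile of 0.192 of random sets, where 250 without had 0.003. With slide means removed it was 0.334 (95th percentile 0.143), and within slides 0.567 in A (0.254) but 0.124 in B (0.183), so that the relation was not past that of random sets in slide B. Slide alone does not account for the excess, since the mean less 1 SD within a slide was at least 0.817 (1.35 ± 0.24 in slide A, 0.99 ± 0.18 in slide B, n = 8 each). Of the 20 miRNAs closest to miR-290, 8 had a probe with a guanine or cytosine run, against 2.33 expected, so most had none. These 20 probes had a median guanine and cytosine content of 67.4%, against 47.8% over all. The miR-290 probe, at 43.5%, did not share it. Signal of the probe other than cluster transcript, such as binding of guanine or cytosine runs, may contribute to the miR-290 ratio and its spread between strains. These arrays cannot settle that hypothesis against strain differences in miR-290 itself.

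Of 100 splits of the 16 arrays of slides A and B into 8 and 8, 2 gave at least the 3 miRNAs of the real slides, the real one included, and the highest other gave 4. That share is under 0.05, but a random split gave more than the real slides and the test was chosen late, so chance is not excluded. The count was 2 with the series table and 0 with median centring and in either channel alone. The slides also hold different strains, so that slide and strain cannot be told apart.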
